A study of Drosophila melanogaster with 12 samples.

How the data were processed

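The series holds RNA-seq of whole adult flies in 4 groups of 3 biological replicates, taken from the sample titles. Total RNA was extracted with TRIZOL and libraries were made with an Illumina TruSeq kit, per the labels' protocols. TopHat, HTSeq and the genome build dm3 are named in the submitters' processing notes, with no versions; the counting mode, the handling of strand and the annotation release are not given in the sources used here. The deposited tables, 1 for autosomal and 1 for X-linked genes, hold raw read counts per RefSeq transcript and, per the file headers, a normalized column per library. Checked on the values, the normalized column is a fraction, the count divided by the column total of its own table, which the authors thus computed separately for each table (largest difference 5.00e-10). The fractions were used for this check only, because the separate totals remove any shift of a whole table against the other, and all tests used the counts of both tables together. Every per-sample column was assigned to a sample from its header.

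Transcripts of 1 gene repeat nearly the same counts, so that reads shared by isoforms are counted once per isoform. The transcript with the highest total count was therefore kept for each gene, a choice made after the values were seen, which gave 14161 genes, 11923 from the autosomal and 2238 from the X-linked table. Gene names that a spreadsheet had turned into date serials were restored through their RefSeq identifiers (3 autosomal, 11 X-linked). Chromosome arms and the order of neighbouring genes came from the RefSeq annotation of Release 6 plus ISO1 MT, a later assembly than dm3, so no coordinates are given. Of 19040 autosomal-table transcripts 17985 matched this annotation by accession and 928 by name only, and of 3698 X-linked ones 3523 and 153. Overlapping and antisense genes cannot be separated where counting ignores strand, and near-identical paralogs such as the lysozymes share reads.

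Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors over all genes, filterByExpr with a minimum count of 10, quasi-likelihood fit and F test of group means over all 12 samples, Benjamini-Hochberg adjustment, threshold 0.05, no minimum fold), which tested 13060 genes. The log2 fold change is the fitted value and its SE is the absolute log2 fold change divided by the square root of F. The X against the autosomes was compared as the difference of median log2 fold changes, with camera of limma 3.58.1 (correlation preset at 0.01, log2 CPM with a prior count of 2), and per library with an exact two-sided permutation test. The comparisons were MSL2 females with control females, MSL2 females with control males, control males with control females, MSL2 males with control males, and the difference of the transgene effect between females and males.

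Samples, comparisons, tests, alternatives and 20 gene lists were fixed before the data were examined. The lists were MSL complex and partners, sex determination, heterochromatin and histone modifiers, eye pigment, photoreceptor, yolk protein, eggshell, germline and maternal, testis-specific, accessory gland, heat shock, immune, Turandot, detoxification, gut, fat body, muscle, neuronal, TM3 marker loci and cytosolic ribosomal protein genes. Of their members 1 germline, 1 detoxification, 1 fat body and 3 of 8 TM3 symbols were not matched. Each list was tested with camera, adjusted over the 20 lists of a comparison, and its called members were counted over all genes and adjusted over the list alone. The text names the MSL complex genes and w in every comparison; in females the 10 largest rises and 10 largest falls among genes called with mean log2 CPM of at least 3 and no overlap between the groups, and the 5 and 5 largest among X-linked genes; in other comparisons the 5 and 5 largest; for the difference between the sexes the 5 and 5 smallest adjusted p; and up to 4 members of a list with the smallest p. Other list members are named where few were called. The mean log2 CPM was taken over all 12 libraries, so that genes high in males alone could pass its minimum. Folds of genes with few counts are given as ratios with a 95% Poisson interval, and 3 counts per library were taken as the floor.

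The edgeR steps were tested on counts simulated from the fitted means and dispersions for MSL2 females against control females, in which 40.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 90.8% of those changed 4-fold were called over 13027 genes, with 9 calls among 12828 unchanged genes. A simulated X shift of 0.20 was recovered as 0.20 and a shift of 0 as -0.01. These counts were drawn with the spread shared over all 12 libraries, which the fit also assumes. They thus cannot show the rate of false calls or of missed changes where females vary more than that. Replicates correlated at 0.982 to 0.997 (Pearson, log2 CPM), and counts of replicates differed beyond sampling noise in every pair (chi-square per degree of freedom of at least 13.9). Alternatives were other scaling (RLE factors of DESeq2, TMM over autosomal genes), no filter or at least 50 counts in 3 samples, only the groups compared, DESeq2 1.42.0, limma-voom, a replicate block, a minimum fold, other sets of autosomal or sex-neutral genes, other set tests, each library left out, and, chosen after seeing the data, isoform sums or means and list counts without the libraries low in eggshell transcripts. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.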

Results

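RNA was sequenced from whole adult Drosophila melanogaster in 12 libraries, which formed 4 groups of 3 biological replicates: control females, control males, females carrying an msl-2 transgene (MSL2 females) and males carrying it (MSL2 males). MSL2 is the limiting subunit of the male-specific lethal (MSL) complex, which coats the single male X chromosome and is not normally assembled in females. Per the labels, the transgene is a P-element insert marked with mini-white, control flies of both sexes carried the chromosome 3 balancer TM3 over a normal homologue, and MSL2 females had 2 chromosomes 3 without it. The genotype of MSL2 males is not given in the sources used here. With 1 transcript kept per gene, the libraries held between 27729411 and 79622278 counts. Control females started at 33849887 counts and held the largest library, control males ranged from 41975875 to 53294740, MSL2 females from the smallest library to 56843908 and MSL2 males from 46030396 to 51458014. At these depths 3 counts in a library, taken as the floor, correspond to between 0.0377 and 0.108 CPM (counts scaled to library size), and intervals and floors cover counting error only. X-linked genes took 17.0% ± 0.254 (SD, n = 3) of the counts in control females, 18.6% ± 0.293 in MSL2 females, 12.95% ± 0.116 in control males and 12.6% ± 0.133 in MSL2 males. Sex accounted for the first principal component of log2 CPM, with 95.98% of the variance.

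The msl-2 transcript itself was read first, as a check of the labels. It reached 526 ± 85.3 CPM (SD, n = 3) in MSL2 females and 490 ± 92.8 CPM in MSL2 males, against 17.4 ± 1.92 CPM in control females and 31.6 ± 0.963 CPM in control males. Every one of the 6 transgenic libraries lay above every control library, the lowest of them at 392 CPM and the highest control at 32.4 CPM. Transcripts of w, the gene that the mini-white marker carries, followed the same grouping, with 18.8 ± 1.10 CPM in MSL2 females, 23.6 ± 3.46 CPM in MSL2 males, 0.717 ± 0.294 CPM in control females and 3.80 ± 0.403 CPM in control males. Reads of the transgene and of the endogenous genes cannot be told apart in these counts.

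**Figure D1:**
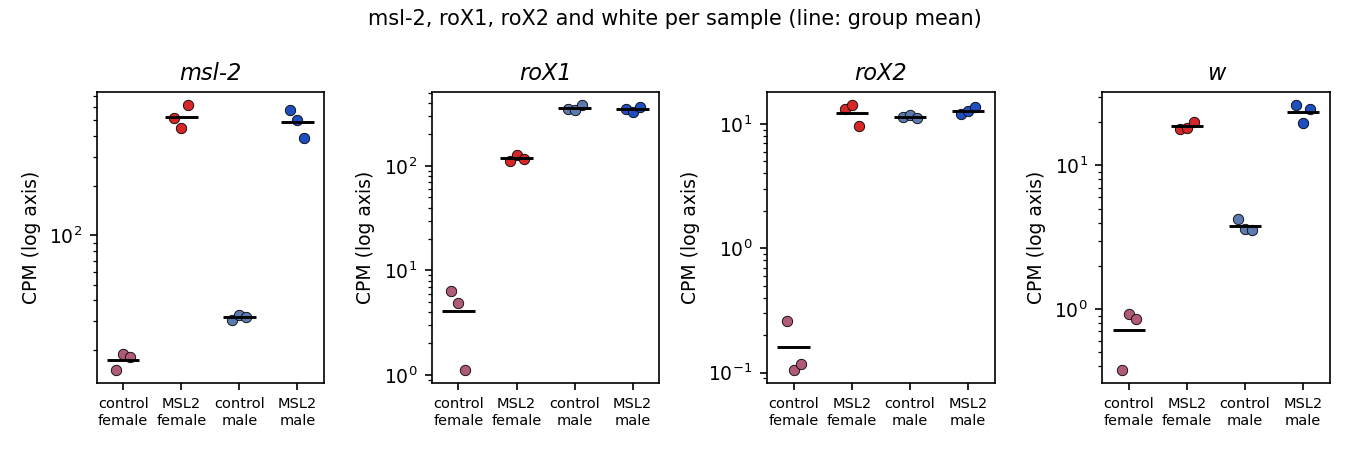
CPM on a log axis of msl-2, roX1, roX2 and w in each library (points) with the group mean (line), n = 3 per group. Both transgenic groups lie far above the controls for msl-2 and w, and MSL2 females lie at the male level for roX2 and between control females and control males for roX1.

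The comparison of MSL2 females with control females asks what ectopic MSL2 does to expression in the sex that normally lacks it. MSL2 females also differed from control females in lacking TM3. The 2 noncoding RNAs of the MSL complex appeared in MSL2 females. The roX2 RNA rose from 24 counts over the control female libraries to 1592 (log2 fold change 6.38 ± 0.25 SE, edgeR adjusted p = 1.75e-07), a ratio per library size of 84.1 with a counting interval of 56.3 to 131.7. The roX1 RNA rose from 4.12 to 119 CPM (4.89 ± 0.46, edgeR adjusted p = 0.000180). The msl-2 transcript (4.92 ± 0.18, edgeR adjusted p = 1.17e-07) and w also rose (4.63 ± 0.23, edgeR adjusted p = 1.11e-06). Among the protein subunits and partners of the complex, msl-3 fell slightly (-0.35 ± 0.09, edgeR adjusted p = 0.0300), and this call was lost without control female 1, control female 2 or MSL2 female 1, with an adjusted p of up to 0.116. No call was made for msl-1 (-0.46, edgeR adjusted p = 0.147), mle (-0.04), mof (0.06) or CG1832, which encodes the X-binding zinc finger protein CLAMP (-0.14). Of the 8 genes of the MSL complex list, 3 were thus higher, 1 lower and 4 not called, with the same 3 and 1 when adjusted over the list alone, and the camera adjusted p of the list was 0.0695.

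X-linked genes as a set were higher relative to autosomal genes in MSL2 females. The median log2 fold change was 0.19 over 2075 X-linked genes and -0.04 over 10967 autosomal genes, a difference of 0.23, or 1.17-fold (camera p = 5.42e-16, and p = 4.62e-06 with an estimated correlation). Of the X-linked genes, 457 rose and 15 fell, 22.7% of those tested, against 123 higher and 141 lower of 5080 genes on chromosome 2 and 275 higher and 322 lower of 5775 on chromosome 3. On the small chromosome 4, 9 of 82 genes rose and none fell. The most frequent ratio of expression between the 2 groups of females was 1.14 for X-linked genes and 0.927 for autosomal genes. Per library, X minus autosome relative to the control female mean was 0.23 ± 0.02 (SD, n = 3) in MSL2 females and 0.00 ± 0.01 in control females. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow.

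**Figure D2:**
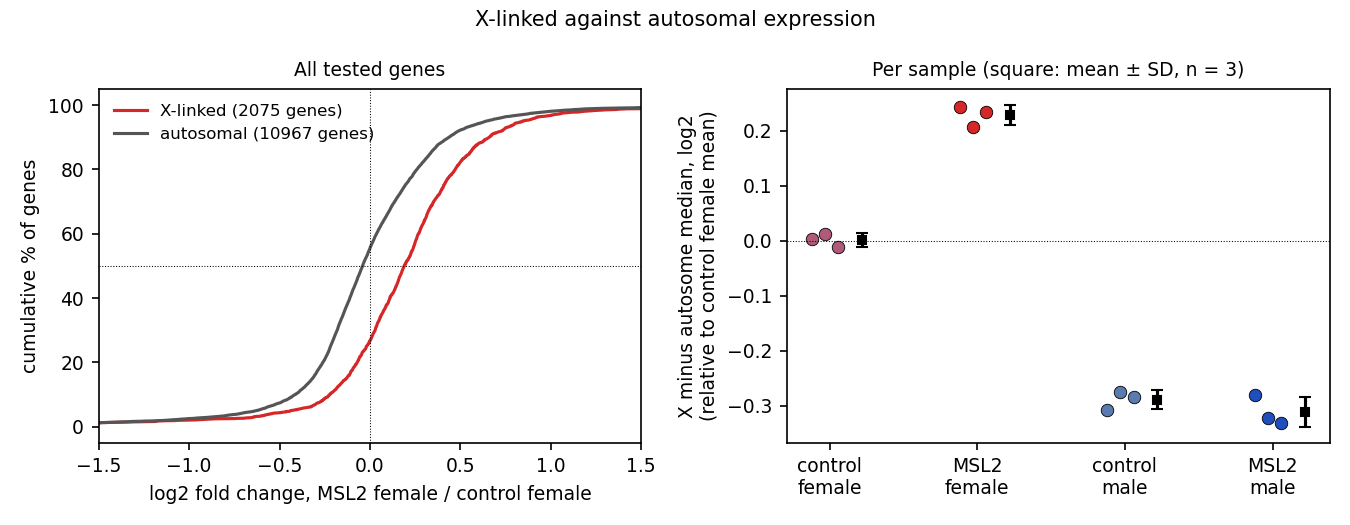
Left, cumulative percentage of tested X-linked and autosomal genes against log2 fold change between MSL2 females and control females; right, X minus autosome median log2 expression of each library (points) relative to the control female mean, with mean ± SD (squares, n = 3). The X-linked curve lies to the right of the autosomal curve by 0.23 at the medians, and the 3 MSL2 female libraries lie between 0.21 and 0.24.

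The largest individual falls in MSL2 females were in a few genes on chromosome 3. CG14087 had 1 count in each MSL2 female library against 301 to 693 counts in control females, a 400-fold lower level (counting interval 137 to 1943, edgeR adjusted p = 2.68e-10). Transcripts of tobi, an insulin-responsive alpha-glucosidase gene, fell from 69.3 to 1.10 CPM (log2 fold change -6.002 ± 0.29, edgeR adjusted p = 1.03e-06), and CG42825 fell from 22.6 to 1.13 CPM (-4.29). The neighbouring lysozyme genes LysC (-3.72), LysD (-3.43), LysB (-3.22) and LysE (-3.10) fell together, for instance LysC from 435 to 33.0 CPM, but these paralogs are near-identical and the split of reads between them is uncertain. CG10407 also fell (-1.81). Among the largest rises were CG13032 (2.75 ± 0.30, ratio 6.86 with a counting interval of 5.15 to 9.30, with 121 CPM in control males), CG14245 (1.61), eIF4E-3 (1.61, ratio 3.09 with an interval of 2.02 to 4.82) and CG14691 (1.57, ratio 2.98 with an interval of 1.65 to 5.61). Ssl had 1 count in each control female library and 3 to 9 in MSL2 females, a ratio of 6.76 with a counting interval of 1.94 to 36.2. Like CG13032, these genes were far higher in males. Control male libraries held 2644 to 3719 counts of eIF4E-3, 808 to 1174 of CG14691 and 677 to 1147 of Ssl. Among X-linked genes CG32564 (1.71) and CG12395 (1.37, ratio 2.68 with an interval of 1.65 to 4.46) followed roX2, roX1 and w in size, and CG1503 (-1.44), Fcp3C (-1.18), CG9672 (-0.59) and CG4198 (-0.59) fell most, together with Cp7Fb (-2.92). CG13186 had 24 counts over the control female libraries and 4 over those of MSL2 females, a 4.73-fold lower level (counting interval 1.63 to 18.8). Control male libraries held 663 to 1011 counts of CG12395 and 1645 to 2371 of CG13186. Several of the calls given above did not hold when 1 library was left out. They were lost without control female 2 for CG32564 (adjusted p = 0.0554) and Fcp3C (0.0505) and without MSL2 female 1 for CG12395 (0.0672). Ssl lost its call without control female 2, control female 3 or MSL2 female 3 (up to 0.0628), Cp7Fb without control female 1, control female 2 or MSL2 female 2 (up to 0.145). CG9672 lost it without either of control females 1 and 2 or MSL2 females 1 and 2 (up to 0.106) and CG4198 without any 1 control female or MSL2 female 2 (up to 0.117). CG13186 lost it without any 1 library but control female 3 (up to 0.155).

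Many genes of phototransduction were called higher in MSL2 females. Of 22 photoreceptor genes, 13 rose, 1 fell and 8 were not called, with 18 higher and 1 lower when adjusted over the list alone (median 0.45, camera adjusted p = 7.47e-08, but adjusted p = 0.685 with an estimated correlation). The rhodopsins moved apart, Rh6 rising (1.14 ± 0.10, edgeR adjusted p = 0.000127, from 32.1 to 70.6 CPM) and Rh5, expressed in the other subtype of the same inner photoreceptor, falling (-1.26 ± 0.09, edgeR adjusted p = 4.05e-05, from 21.0 to 8.79 CPM). Rh4 (0.75) and the light-activated channel gene trp (0.65) rose. The number of higher genes fell to 6 without control female 1, 7 without control female 2, 8 without MSL2 female 2 and 3 when the fit held only these 6 libraries. The medians in these settings were 0.37, 0.43, 0.47 and 0.45. Without MSL2 female 3, 16 genes were higher and the median was 0.56. Without MSL2 female 1, the library low in eggshell transcripts, 10 were higher and the median was 0.32. The medians of the muscle and neuronal lists also fell without it, and those of the eggshell and germline lists lay closer to 0. Of 14 eye pigment genes, w and dor (0.32) were higher and 12 not called, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.685 with an estimated correlation). The call of dor was lost without control female 1 (adjusted p = 0.0689) or MSL2 female 2.

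Few genes of the ovary lists were called. Of 25 eggshell genes, encoding chorion and vitelline membrane proteins, none rose, 3 fell (Fcp3C, Cp7Fb and psd at -1.62) and 22 were not called, with 0 and 4 adjusted over the list alone (median -1.84, camera adjusted p = 2.33e-06, adjusted p = 0.685 with an estimated correlation). MSL2 female 1 held 0.431 CPM of Cp36 transcript against 92.8 and 81.1 CPM in the other MSL2 females, and without it the eggshell median was -1.32 with 7 genes lower. The call of psd was lost without any 1 of the control females or without MSL2 female 2 (adjusted p of up to 0.121). Of 43 germline and maternal genes, only bam, a germline differentiation factor, was called (-0.97 ± 0.15, edgeR adjusted p = 0.00304), also when adjusted over the list alone (median -0.32, camera adjusted p = 0.000651, adjusted p = 0.685 with an estimated correlation). Without MSL2 female 1 the germline median was -0.07. No call was made among the 3 yolk protein genes (median -0.56, camera adjusted p = 0.231), where edgeR gave 1 gene at an unadjusted p under 0.05 and DESeq2 none.

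Of 45 gut genes, 1 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.00823, adjusted p = 0.685 with an estimated correlation). All 6 were lysozymes, with LysD, LysB, LysE, LysP (-0.72) and LysS lower and LysX higher. Of 92 cytosolic ribosomal protein genes, 2 rose and 5 fell, the same over the list alone (median -0.19, camera adjusted p = 1.54e-07, adjusted p = 0.685 with an estimated correlation). RpS19b rose by 1.15, and RpL23 (-0.32), RpS27 (-0.31) and RpS18 (-0.31) fell. The last 3 calls were lost without control female 1, control female 2 or MSL2 female 2, and those of RpS27 and RpS18 also without MSL2 female 1 (adjusted p of up to 0.122). Without MSL2 female 1 the list had 1 gene higher and 1 lower. Of 31 heterochromatin and histone modifier genes, only MBD-R2 fell (-0.29), with 1 higher and 7 lower adjusted over the list alone (median -0.20, camera adjusted p = 0.000324, adjusted p = 0.685 with an estimated correlation). The call of MBD-R2 was lost without either of control females 1 and 2 or MSL2 females 1 and 2 (adjusted p of up to 0.167). Of 56 detoxification genes, 3 rose and 7 fell, with 6 and 11 over the list alone (camera adjusted p = 0.334). The cytochrome P450 genes Cyp6a8 (-1.36) and Cyp6a2 (-0.80) fell and Cyp4d2 (0.93) and Cyp4d14 (1.16) rose. Of 31 immune genes, the recognition protein genes PGRP-SD (0.81) and PGRP-SA (0.76) and the antibacterial peptide gene CecA1 (2.17) rose and none fell, the same over the list alone (camera adjusted p = 0.305). The call of CecA1 was lost without any 1 of the control females or without MSL2 female 2 (adjusted p of up to 0.0603).

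Of 27 neuronal genes, Cha (0.74) and nAcRbeta-64B (0.46) rose, also over the list alone (median 0.18, camera adjusted p = 0.00823, adjusted p = 0.685 with an estimated correlation). Without MSL2 female 1 the neuronal median was 0.07, neither of them was called and 1 other gene was lower. Of 26 muscle genes none was called by edgeR, 9 had an unadjusted p under 0.05, and DESeq2 called 2 higher and 1 lower (median 0.34, or 0.09 without MSL2 female 1, camera adjusted p = 0.00445, adjusted p = 0.685 with an estimated correlation). Single calls were made for Fbp1 of 24 fat body genes (1.04, camera adjusted p = 0.0883), Hsc70-5 of 23 heat shock genes (-0.22, camera adjusted p = 0.0919) and CG30488 of 34 accessory gland genes (0.90, camera adjusted p = 0.523). None of them was made when adjusted over the list alone. The call of Cha was lost without control female 1, control female 2 or MSL2 female 1 (adjusted p of up to 0.0972), that of nAcRbeta-64B without these or MSL2 female 2 (0.106). That of CG30488 was lost without control female 1, control female 3, MSL2 female 1 or MSL2 female 2 (0.109), and those of Fbp1 (0.155) and Hsc70-5 (0.146) without any 1 library but MSL2 female 3. No gene was called among 63 testis-specific genes (3 with an unadjusted p under 0.05, DESeq2 1 higher, camera adjusted p = 0.639) or 11 sex determination genes (2 unadjusted, DESeq2 none, camera adjusted p = 0.517). The same holds for 5 Turandot stress genes (1 unadjusted, DESeq2 1 lower, camera adjusted p = 0.334) and 5 TM3 marker loci (0 unadjusted, DESeq2 none, camera adjusted p = 0.385). The same counts of 0 held for these lists when adjusted over the list alone. The medians of the MSL complex, sex determination, testis and detoxification lists change sign with the scaling.

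Over all 13060 genes tested, edgeR called 1344 at an adjusted p under 0.05, 865 higher and 479 lower (64.4% higher), and 208 of them differed by over 2-fold. With scaling factors from autosomal genes alone, 78.4% of 1552 calls were higher. The count fell to 543 without control female 2, 584 without control female 1, 826 without MSL2 female 2 and 156 when only these 6 libraries were fitted. It rose to 2851 without MSL2 female 3 and 2054 with DESeq2. X-linked calls stayed mainly higher (72 higher and 0 lower in the fit of 6 libraries).

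**Figure D3:**
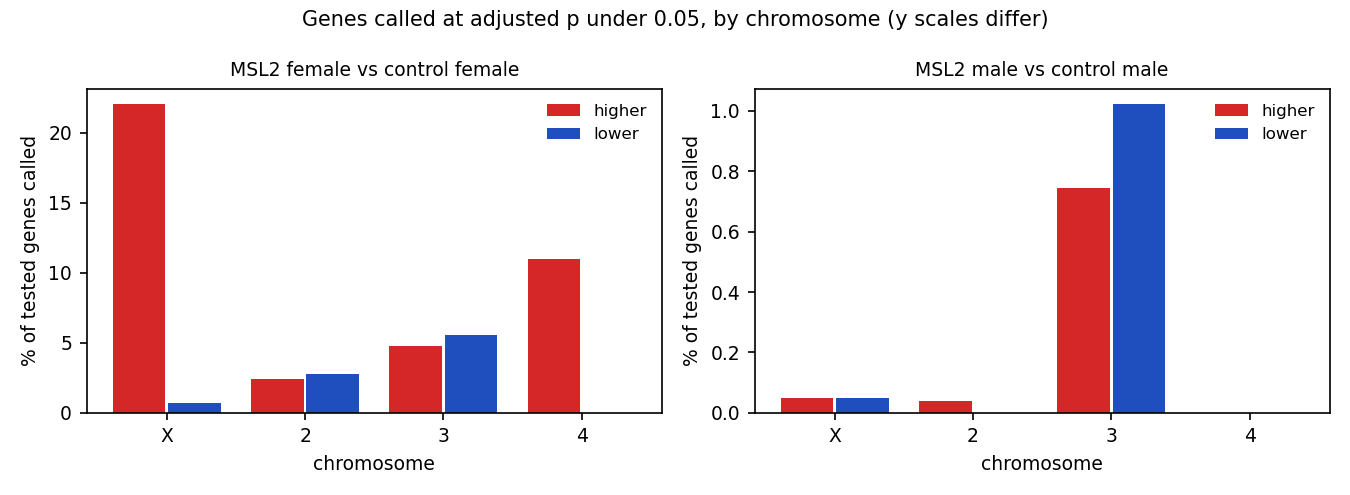
Percentage of tested genes called higher (red) and lower (blue) on each chromosome at an adjusted p under 0.05, in females (left) and males (right), with different y scales. In females 457 of 2075 X-linked genes were higher, and in males nearly all calls lay on chromosome 3.

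The series also sets MSL2 females against control males, the sex that makes MSL2 from its own gene. MSL2 females did not differ from control males in roX2 (12.3 against 11.4 CPM, log2 fold change 0.10, edgeR adjusted p = 0.601) and had less roX1 (119 against 359 CPM, -1.60 ± 0.39, edgeR adjusted p = 0.00333). They had more msl-2 (4.05), w (2.30), msl-1 (1.52), mof (0.58) and CG1832 (0.21), while msl-3 was not called (-0.15) and mle was (0.17) but not without control male 3 or MSL2 female 2 (adjusted p of up to 0.174). The MSL complex list thus had 5 genes higher, 1 lower and 2 not called, the same when adjusted over the list alone (camera adjusted p = 0.316). The 6 lists given next lay in the direction of the difference between control females and control males. Of 25 eggshell genes 21 were higher (psd 7.50, Vm26Aa 7.04), of 43 germline genes 37 were higher and 3 lower (vas 4.62), and the 3 yolk protein genes were higher (Yp1 7.72, Yp2 7.55). Of 63 testis genes 62 were lower and 1 higher (Mst35Bb -8.29), of 34 accessory gland genes 33 were lower (Acp32CD -8.01), and 85 of 92 ribosomal protein genes were higher and 7 lower, among the latter RpL22-like (-7.18) and RpL10Aa (-8.04). The counts of these 6 lists were the same when adjusted over the list alone, and their camera adjusted p were 0.00522, 4.30e-07, 0.0118, 3.93e-20, 5.58e-13 and 5.06e-14. With an estimated correlation none of them passed, the lowest adjusted p being 0.299.

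X-linked genes lay 0.52 above autosomal genes in median log2 fold change between MSL2 females and control males (0.54 against 0.03, 1.43-fold, camera p = 3.62e-06, and p = 0.000261 with an estimated correlation). The most frequent ratio was 1.58 for X-linked genes and 1.06 for autosomal genes. Over all genes 5035 were higher and 4090 lower, but the balance turned with RLE size factors (4453 higher, 4541 lower), with DESeq2 (4543, 4600) and among calls over 2-fold (1723, 2881). The largest rises by the fixed rule were CG42705 (247-fold, counting interval 144 to 465), CG17012 (7.77), osk (7.74), which encodes the posterior determinant of the egg, Yp1 and CG17234 (188-fold, counting interval 105 to 378). The largest falls were in genes nearly absent from MSL2 females, with 2 to 6 counts over 3 libraries. CG13186 was 1383-fold lower (counting interval 540 to 5079), CG42692 1090-fold (301 to 9002), CG34210 732-fold (250 to 3553), CG14840 667-fold (260 to 2450) and CG5388 646-fold (296 to 1761). Scaling on autosomal genes moved the median of all genes from 0.09 to 0.22, which small fold changes should be read against.

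Control males against control females gives the normal sex difference. The roX1 RNA (log2 fold change 6.49 ± 0.49, edgeR adjusted p = 2.34e-07) and roX2 RNA (6.28 ± 0.25, ratio 80.1 with a counting interval of 53.6 to 125, edgeR adjusted p = 4.64e-10) were higher in males, as were w (2.33) and msl-2 (0.86). In males msl-1 (-1.98), mof (-0.52), CG1832 (-0.34) and mle (-0.21) were lower and msl-3 was not called (-0.21, edgeR adjusted p = 0.0510). The MSL complex list had 3 higher, 4 lower and 1 not called, with 3 and 5 over the list alone (camera adjusted p = 0.861). The switch gene Sxl was lower in males (-1.91) and dsx higher (1.16, a call lost with isoform sums or means), in a sex determination list with 3 of 11 higher and 8 lower, also over the list alone (camera adjusted p = 0.0861). Of 63 testis genes 61 rose (Mst35Bb 8.12) and 1 fell, with 62 and 1 over the list alone, and all 34 accessory gland genes rose (Acp32CD 7.94), also over the list alone (camera adjusted p = 1.18e-18 and 2.10e-12). Of 25 eggshell genes 24 fell, of 43 germline genes 38 fell and 2 rose, and all 3 yolk genes fell, each the same over the list alone (camera adjusted p = 3.07e-05, 1.30e-08 and 0.0101). Ribosomal protein genes had 85 lower and 7 higher, heterochromatin genes 28 lower and 1 higher, both also over the list alone (camera adjusted p = 9.13e-16 and 1.44e-06). Gut genes had 27 lower and 2 higher, with 23 and 1 over the list alone, and neuronal genes 19 higher and 2 lower, also over the list alone (camera adjusted p = 0.0184 and 0.0486). With an estimated correlation none of these lists passed, the lowest adjusted p being 0.456.

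The largest sex differences lay in genes near the floor in control females. CG32833 was 1463-fold higher in males (counting interval 405 to 12087), CG13494 1072-fold (366 to 5199), Ssl 1038-fold (355 to 5037), CG30325 879-fold (300 to 4264) and glob2, a testis globin gene, 792-fold (417 to 1732). The largest falls were psd (572-fold, counting interval 357 to 983), Cp38 (-8.92), Cp36 (-8.64), Cp19 (-8.51 ± 1.75, with 283-fold from the counts and an interval of 216 to 380) and Vm26Aa (-8.50), all eggshell genes. Of all genes 4490 were higher and 4906 lower, and this balance also turned with RLE size factors (4866 higher, 4640 lower), with DESeq2 (4932, 4710) and among calls over 2-fold (2819, 1949). The median log2 fold change of X-linked genes was -0.23 and that of autosomal genes 0.05, a difference of -0.28 (camera p = 0.00830, and p = 0.00774 with an estimated correlation), although the mean over X-linked genes was above 0 (0.43) like that over autosomal genes (0.96).

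MSL2 males against control males compares males with and without the transgene, where the complex is already present. Control males carried TM3 and the genotype of MSL2 males is not given. A genotype difference on chromosome 3 thus cannot be told apart from the transgene. Apart from msl-2 (log2 fold change 3.95 ± 0.17, edgeR adjusted p = 1.32e-06) and w (2.63 ± 0.20, edgeR adjusted p = 8.94e-05), 102 of the 106 genes called lay on chromosome 3. The largest falls were in genes that had also fallen in MSL2 females, tobi (-5.88, from 110 to 1.86 CPM), CG42825 (-3.93, from 19.3 to 1.27 CPM), LysC (-2.51), LysD (-2.22) and LysB (-2.08), with the same uncertainty between the lysozyme paralogs. The largest rises after msl-2 and w were CG31041 (2.11), CG14567 (1.405) and CG31468 (1.15). The roX1 (-0.04) and roX2 (0.16) RNAs, msl-1 (0.04), msl-3 (-0.29), mle (-0.04), mof (-0.10) and CG1832 (0.07) were not called. The 2 calls outside chromosome 3 other than msl-2 and w were CG15155 on chromosome 2 (0.71, edgeR adjusted p = 0.0481) and mRpL49 on the X (-0.32, edgeR adjusted p = 0.0254), named after their values were seen.

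X-linked genes as a set did not differ detectably between MSL2 males and control males (X minus autosome -0.02, camera p = 0.139, and p = 0.0830 with an estimated correlation). Per library the values were -0.31 ± 0.03 (SD, n = 3) in MSL2 males and -0.29 ± 0.02 in control males, with p = 0.3 in the exact two-sided permutation test. Of 45 gut genes 4 fell, LysP (-1.12), LysD, LysB and LysS, with 1 higher and 5 lower over the list alone (camera adjusted p = 0.0518). Of the 22 photoreceptor genes edgeR called none, 7 had an unadjusted p under 0.05, DESeq2 called 3 higher, and 4 were higher when adjusted over the list alone (median 0.20, camera adjusted p = 1.28e-08, adjusted p = 0.662 with an estimated correlation). The 92 ribosomal protein genes had no call, 18 at an unadjusted p under 0.05 and none by DESeq2 or over the list alone, and a camera adjusted p of 1.69e-19 toward lower values (median -0.14, adjusted p = 0.662 with an estimated correlation). The 24 fat body genes had no call, 4 at an unadjusted p under 0.05, 3 higher by DESeq2 and 3 over the list alone (median 0.18, camera adjusted p = 0.00613, adjusted p = 0.662 with an estimated correlation). Over all genes 46 rose and 60 fell. The number of calls fell to between 41 and 57 without any 1 of the 6 libraries and rose to 287 when only these 6 were fitted and to 292 with DESeq2. The call of CG31468 was lost without any 1 library but MSL2 male 2 (adjusted p of up to 0.0807), and those of LysS (0.118) and of GstD7, the only gene called of 56 detoxification genes (-1.37, 0.162), without any 1 library but control male 1. The MSL complex and eye pigment lists each held 1 call, msl-2 and w (camera adjusted p = 0.346 and 0.0635).

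The transgene effect, meaning all differences of transgenic from control flies, was then compared between the sexes in 1 test of the difference. It was larger in females for roX2 (difference 6.21 ± 0.30, edgeR adjusted p = 2.84e-06) and roX1 (4.93 ± 0.58, edgeR adjusted p = 0.00601), for the mitochondrial ribosomal protein genes mRpL49 (0.75) and mRpL14 (1.07), and for msta (0.98), all X-linked. It was more negative in females for CG14087 (-8.28 ± 0.20, edgeR adjusted p = 2.47e-09), Rh5 (-1.28 ± 0.13, edgeR adjusted p = 0.00271), CG11253 (-1.31), CG1503 (-1.47) and LysE (-2.21). CG14087 had 1 count in each MSL2 female library and 501 to 575 in MSL2 males. The genotype of MSL2 males is not given. For chromosome 3 genes such as CG14087 a genotype difference thus cannot be told apart from the transgene. The MSL complex list held 2 calls, roX1 and roX2, and 3 over the list alone (camera adjusted p = 0.0333, adjusted p = 0.959 with an estimated correlation), with msl-1 (-0.49), msl-3 (-0.06), mle (0.00), mof (0.16) and CG1832 (-0.21) not called. Of 22 photoreceptor genes 1 was higher and 1 lower, Rh6 (0.93) and Rh5, with 4 and 1 over the list alone (camera adjusted p = 0.00157, adjusted p = 0.959 with an estimated correlation). The call of Rh6 was lost without control male 1 or any 1 MSL2 male (adjusted p of up to 0.0524). Of 25 eggshell genes edgeR called none, also over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 1 lower (median -1.51, camera adjusted p = 1.97e-05, adjusted p = 0.959 with an estimated correlation), with the low MSL2 female 1 among the libraries. The heterochromatin and germline lists toward lower values, and the muscle and neuronal lists toward higher, had no call. Their camera adjusted p were 0.00157, 0.00634, 0.00157 and 0.0333, and 0.959 with an estimated correlation. The difference in msl-2 did not pass (0.96, edgeR adjusted p = 0.0609), and that in w did (2.002, edgeR adjusted p = 0.0147), but not without MSL2 male 3 (adjusted p = 0.0524). X-linked genes as a set differed, with X minus autosome 0.26 higher in females (camera p = 5.65e-21, and p = 1.49e-06 with an estimated correlation). Of 165 genes called, 138 had the more positive effect in females, 114 of them on the X, and 27 the more negative effect. The calls of CG11253, CG1503 and LysE were lost without MSL2 male 1 or MSL2 male 3 (adjusted p of up to 0.0524). The count ranged from 23 without MSL2 male 3 to 250 without MSL2 female 3, with values of 36 to 64 without MSL2 male 1 or 2, any 1 control male, control female 1 or control female 2.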

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

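The comparison of the transgene effect between females and males was planned as a test of the difference, and it set apart the X-linked genes as a set and 10 of 30 genes. The 30 were the MSL complex genes, w and the genes with the largest changes in females. Picking genes by their change in females favours such a difference, and of all 13060 genes 165 were called. On chromosome 3 the effect can include a genotype difference, as the genotype of MSL2 males is not given. X minus autosome was 0.26 higher in females (0.23 in females and -0.02 in males, camera p = 5.65e-21, and p = 1.49e-06 with an estimated correlation). The differences in log2 fold change were 6.21 for roX2, 4.93 for roX1, 2.002 for w, 2.79 for CG13032, 1.24 for eIF4E-3, 1.525 for CG14691, -8.28 for CG14087, -2.21 for LysE, -1.73 for CG10407 and -1.47 for CG1503, each past the edgeR adjusted p threshold of 0.05 with all libraries. Without any 1 library roX2, roX1, CG13032 and CG14087 stayed past it (adjusted p of up to 0.0362). The call was lost for w without MSL2 male 3 and for LysE and CG1503 without MSL2 male 1 or 3 (adjusted p of up to 0.0524). It was lost for CG10407 without any 1 male library, control female 1 or control female 2 (up to 0.115), and for eIF4E-3 (up to 0.0987) and CG14691 (up to 0.136) without any 1 library but MSL2 female 1. The count of all genes called fell from 165 to 23 without MSL2 male 3. Control females had less w transcript (0.717 CPM) than control males (3.80 CPM).

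All the tests of the next 3 patterns except that of library size were chosen after the pattern was seen. Of the genes called in males 102 lay on chromosome 3, on which control flies carried TM3 (1.77% of its tested genes, 95% binomial interval 1.44 to 2.14, against 0.0394% on chromosome 2), which argues against a transgene effect spread evenly over the autosomes as the source of the male calls. Of the 102 genes 91.2% (95% binomial interval 83.9 to 95.9) had the same sign in females, as did all 64 called in both sexes, which a genotype difference on chromosome 3 needs but a transgene effect in both sexes would give too. Of the genes called in females 84.4% on chromosome 3 and 79.5% on chromosome 2 had the same sign in males (all tested genes 62.29% and 60.02%), and of those over 2-fold 80.2% of 126 and 59.1% of 44, a difference that was not tested. Loss of reads from TM3 alleles in mapping, with controls TM3/+ per the labels, can raise MSL2 flies by 2-fold at most, which argues against it for 9 of the 43 higher genes (lower 95% bound over 2-fold) and leaves it open for the others. For the 57.8% of calls that were lower it stays open in males, whose genotype is not given. But 37 of these 59 genes, among them tobi, CG42825 and LysC, were also called lower in MSL2 females. Lost TM3 reads could only raise these genes in MSL2 females, so these falls in females are not reads lost from TM3 alleles. They may belong to the transgene or to the genotype difference on chromosome 3. Reads lost from the chromosomes 3 of MSL2 females were not tested.

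The rise of X-linked genes against autosomal genes in MSL2 females was not that of a few genes, since 76.8% of X-linked genes lay above the autosomal median, against 40.3% in males. Counts scaled between libraries cannot tell a rise of X-linked genes from a fall of autosomal genes. Over genes under 2-fold between the control sexes X minus autosome was 0.27, so that genes over 2-fold between the sexes do not account for it. Genes expressed in the ovary can remain in that set, so a different share of ovary is not excluded. With all libraries thinned to the depth of the smallest, 27729411 counts, X minus autosome was 0.23. Thinning keeps the expected share of each gene in its library, so that this value could hardly move. It cannot tell whether a bias tied to library size accounts for the difference. The value of -0.0240 in MSL2 males would speak against TM3 as the cause if those males lacked TM3 like MSL2 females, but with their genotype not given it cannot tell. The biological explanation in the design, ectopic MSL2 acting on the X through roX RNAs, is consistent with the rises of roX2 and roX1 and with an X minus autosome of 0.23, but binding was not measured here.

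MSL2 female 1 stood apart in eggshell transcripts, with a median deviation of -4.60 log2 from the other MSL2 females over 25 genes. A mislabelled sample does not account for it, since its msl-2 level was 15.8 times that of the highest control library (513 against 32.4 CPM) and its testis genes lay 8.03 log2 below MSL2 males. A smaller share of the whole ovary was tested as an equal fall of eggshell and germline genes. Germline genes deviated by -1.16 and yolk genes by -0.37, an eggshell minus germline difference of -3.44. But these lists also differed unequally between control males and control females, with medians of -7.31 for eggshell and -3.13 for germline genes. Unequal falls thus cannot exclude a smaller share of the ovary. Control female 3 was also low in the late chorion transcript Cp15 (8.41 CPM, against 550 and 385 CPM). No biological explanation was tested, since the labels give no age or egg stage per library.

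Relabelling the samples was a test written before its result. For MSL2 females against control females the real grouping called 1344 genes and the highest other 8; for MSL2 females against control males, control males against control females and MSL2 males against control males it called 9125, 9396 and 106 genes and the highest other none. In each the real grouping was the only 1 of 10 to call as many, and 10 are too few for a share under 0.05. For the difference between the sexes 3 of 100 groupings, the real one among them, called at least the real 165. The highest other called 1016, a grouping that swaps all 3 male labels and so tests the sum of the 2 transgene effects. The next called 171. Both kept all 3 MSL2 female labels and so still held the female difference. Groupings that mixed the real groups within a sex carry the limit given above.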

How the results depend on the processing

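X minus autosome kept its sign and side of the threshold under every alternative run for it (not DESeq2, limma-voom or the minimum fold) for MSL2 females against control females (0.22 to 0.27), against control males (0.39 to 0.55) and control males against control females (-0.30 to -0.15). For MSL2 males it stayed between -0.04 and -0.01, and only with arms 2L and 2R as the autosomal set did it pass (-0.0298, n = 2075 X-linked genes, camera p = 0.0421). Counts of calls moved more, and the cause was not tested except that the minimum fold removes calls by construction. A replicate block left 669, 51 and 10 genes for MSL2 females against control females, MSL2 males against control males and the difference between the sexes, but replicate numbers do not pair the samples, since only 4 of 12 correlated best with their own number. Only the groups compared, with the spread taken from those 6 libraries and not from all 12, gave 156 in females and 287 in males. DESeq2 gave 2054, 292 and 421. The chi-square per degree of freedom between replicates, which also grows with depth, reached 308 in MSL2 females and 118 in control females. It reached 63.5 in control males and 70.5 in MSL2 males. Adjusted p in females under the shared spread may thus be too small. With the spread of the 6 compared libraries alone, calls fell from 1344 to 156 in females and rose from 106 to 287 in males. A shared spread too small for females and too large for males would move both counts this way. That fit also differs in the number of libraries and the genes tested, and these were not separated. A minimum log2 fold change of 1 left 208, 4604, 4768, 48 and 50 in the 5 comparisons. Leaving out 1 library gave 543 to 2851 genes in females, 41 to 57 in males and 23 to 250 for the difference. In all 129 of 162 results under an alternative were the same and 0 reversed. A count of calls was labelled only the same or moved, so that only X minus autosome could reverse. The balance of higher and lower calls had no label. As given above, it turned with some settings for MSL2 females against control males and for control males against control females. Of 7778 values of named genes 7431 were the same, 226 weaker, 120 stronger and 1 reversed, TotC between MSL2 females and control males, not called and at -0.38 with all libraries, -0.97 without MSL2 female 3 and 1.34 without control male 1 (edgeR adjusted p = 0.0470). With an estimated correlation 36 of 100 gene list results were lost, which were all that had passed, so that none passed. The fry test, which tests against no change and not against other genes, turned the direction of 1, the MSL complex list between control sexes (fry adjusted p = 0.00527, camera adjusted p = 0.861). Isoform sums and means were added after seeing the data. The pseudocounts planned for normalized values were not run, since counts were tested, and the prior count of 2 behind camera was not varied.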

Other observations

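Which genes to name here was chosen after their values were seen. On chromosome 4, which has its own chromosome-wide regulator, 9 genes rose in MSL2 females (CG11155, CG1674, CG1909, CG32017, CG32021, Kif3C, dpr7, mav and yellow-h) and the median over 82 genes was 0.12, against -0.04 on chromosomes 2 and 3 (camera p = 2.13e-05, but p = 0.257 with an estimated correlation). In males it was 0.06 against 0.01 (camera p = 0.00121, and p = 0.380 with an estimated correlation). Photoreceptor genes had a positive median in both sexes, 0.45 in females and 0.20 in males, in flies that differ in w level.

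The tests of neighbouring genes and of expression level were written before their results, but the margin of 2 SE for the first was added after its result was seen. Log2 fold changes in females of adjacent X-linked genes had a rank correlation of 0.174 (permutation p = 1.00e-04 over shuffled gene orders, the smallest possible with the number drawn), against 0.144 on 2L, 0.164 on 2R, 0.151 on 3L and 0.133 on 3R, so that the test cannot tell whether X-linked neighbours rise together beyond what autosomal neighbours do. The X minus autosome difference was 0.21, 0.24, 0.24 and 0.23 over 4 classes of expression from low to high, a range of 0.03 (0.0291), and so did not depend on expression level.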
